A study of Mus musculus with 35 samples.

How the data were processed

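Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was analysed in 35 libraries from primary macrophages grown from the bone marrow of female C57BL/6 mice. The cells were unstimulated or stimulated with lipopolysaccharide (LPS), a component of the outer membrane of Gram-negative bacteria. The 6 targets were the NF-κB subunits p50 and p65, the transcription factor ATF3, acetylated histone H4 (H4ac), RNA polymerase II (Pol II) and histone H3 trimethylated at lysine 27 (H3K27me3). Per the labels' protocols, fixed chromatin was sonicated, precipitated with an antibody to the target and sequenced from single ends on an Illumina Genome Analyzer. Target, stimulation and time came from the labels, which put the libraries in 20 groups. The letter in a title (A, B, C, D or X) served as the replicate name. Nothing in the labels says that replicates came from separate animals or cultures, so p-values measure only the spread between these libraries, which may be technical.

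Each library had 1 deposited list of genomic regions without a header line. The lists held a position, a score and a scale number for each region. The score per region is the authors' own, as deposited, and served only to rank regions within a list. Genome build mm9 was named in the submitters' processing notes, and no region ended beyond the mm9 length of its chromosome. The aligner, the method that called the regions and its thresholds are not given in the sources used here. Each list belonged to 1 library, so lists were treated as made per library. The lists hold no read counts, so sequencing depth is unknown, and a region missing from a list was read as not listed rather than as unbound. Intervals on shares cover counting error over regions only.

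The lists were nested, with regions of 100 bp to 133 Mb, scale numbers from 2 to 46 and coordinates in steps of 10 bp. Of 250088 regions, 62700 were wider than 10 kb and 16877 wider than 100 kb, and 44144 exceeded the width limit of their target. Merging overlapping regions of every width would join most others into a few very wide ones, so regions up to 10 kb were used for p50, p65, ATF3 and H4ac, and regions up to 100 kb for Pol II and H3K27me3. This width limit departs from the plan fixed before the data were examined, which used every region, and results with all widths and with limits of 1 kb and 10 kb were computed beside it. Numbers of regions per library count every listed region. Coordinates are 1-based, on mm9.

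Regions of a target were merged across its libraries where they overlapped by at least 1 bp, and a library held a merged region if 1 of its own regions overlapped it by at least 1 bp. A p50 region was called gained if at least 3 LPS lists and no unstimulated list held it, and lost if at least 2 unstimulated lists and no LPS list held it. For H4ac, Pol II and p65, a region was called gained at a time if every list of that time and no unstimulated list held it, and lost in the opposite case. For p50 the count was compared with all 35 ways to split the 7 libraries into 4 and 3. For H4ac it was compared with the other ways to split 4 libraries 2 against 2. Pol II, p65 and H3K27me3 had 1 unstimulated library each, and their changes were planned as values with no test run. Numbers of regions and shares per library were compared by exact two-sided permutation tests. Similarity of H4ac lists was the Jaccard index over base pairs, tested one-sided over all ways to pair the 8 libraries.

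Overlap between targets was the share of a library's regions, up to the width limit and joined where they overlapped, that touched a merged region held by at least 2 libraries of the other target. It was set against 1000 random placements of the same regions on the same chromosomes, for which the smallest possible two-sided p is 0.002. There were 175 such tests, adjusted by the Benjamini-Hochberg method. Changed regions were first compared by Fisher's exact test with regions held in both conditions, and gained regions were then compared directly with lost ones in 47 tests, with the same adjustment and 200 random placements of each set. Neither family was planned before the data were examined. The direct comparison was chosen after the first had been seen, because regions held in both conditions differed in width from changed ones. Gained and lost regions differed in width as well, so the direct comparison is not matched for width. In the first family 83 tests passed an adjusted p of 0.05, and in the second 36. Regions are not replicates, so these tests describe the lists and not the variation between cultures.

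For the share of changed regions that kept their state at another time, which uses the same unstimulated lists in both comparisons, 100 sets of unchanged LPS lists were simulated, a comparison also added after seeing the data. Each was drawn region by region from the share of all lists that held the region, scaled to the length of the real list. The same share for independent lists was computed too. The count of gained p50 regions was tested on simulated data with 2478 regions, of which 200 were planted as gained. The other regions were drawn from how often each region and each library was listed, with no LPS effect of their own. The count recovered 192 planted regions (96%) and also called 172 of the others.

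Named regions followed a rule fixed before the data were examined. It takes the 5 gained and 5 lost regions per target with the best mean rank of the authors' score over the lists that hold them, and the 3 best-ranked regions held by every list of the target. It was applied to regions up to the width limit, which was chosen later. Of the 66 named regions, 24 kept their call with all widths as first planned, 40 with the narrower limit and 49 with at least 50% of the merged region covered. The gene table at hand is on assembly GRCm38.p6 and the regions are on mm9, so occupancy of gene lists, nearest genes and markers of other cell types were not analysed here. Regions are therefore given by position without a gene, exon or intron.

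Alternatives were the better-scored 50% of each list, covered base pairs in place of the number of regions, and at least 50% of a region covered. Others joined regions within 1000 bp, used 1 kb bins, required every library of a group, used the letter as a block, took the union of all libraries of a target, shifted each region within 1 Mb, or left out each library in turn. Added after seeing the data were the width settings, lists of equal length, covered base pairs up to the width limit, the p65 set from letter X with the ATF3 set from letter A, and p50 without both letter D libraries. Leaving out single libraries from the overlap results and every alternative of the gained against lost comparison were also added then. Titles open with numbers that read as dates, and these were treated as possible batches. Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.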

Results

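The series profiled macrophages before and after LPS, which activates them through Toll-like receptor signalling, and asked where transcription factors, polymerase and histone marks lay on the genome. The p50 subunit of NF-κB was profiled in 3 unstimulated libraries and 4 libraries at 60 min of LPS. The p65 subunit had 1 unstimulated library and 2 each at 60 and 120 min, and ATF3, a transcription factor induced by stress, had 3 libraries at 240 min. H4ac, a mark of active chromatin, had 2 libraries each at 0, 60, 120 and 240 min. Pol II had 1 unstimulated library, 2 each at 60 and 240 min and 1 each at 120 and 360 min. H3K27me3, the mark left by Polycomb repressive complexes, had 1 unstimulated library and 1 each at 120, 240 and 480 min. A further H3K27me3 library is labelled 480 min, with 60 min and a 7 h delay in its title. The lists held 255 to 28522 regions. Read depth is unknown for every library.

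**Figure D1:**
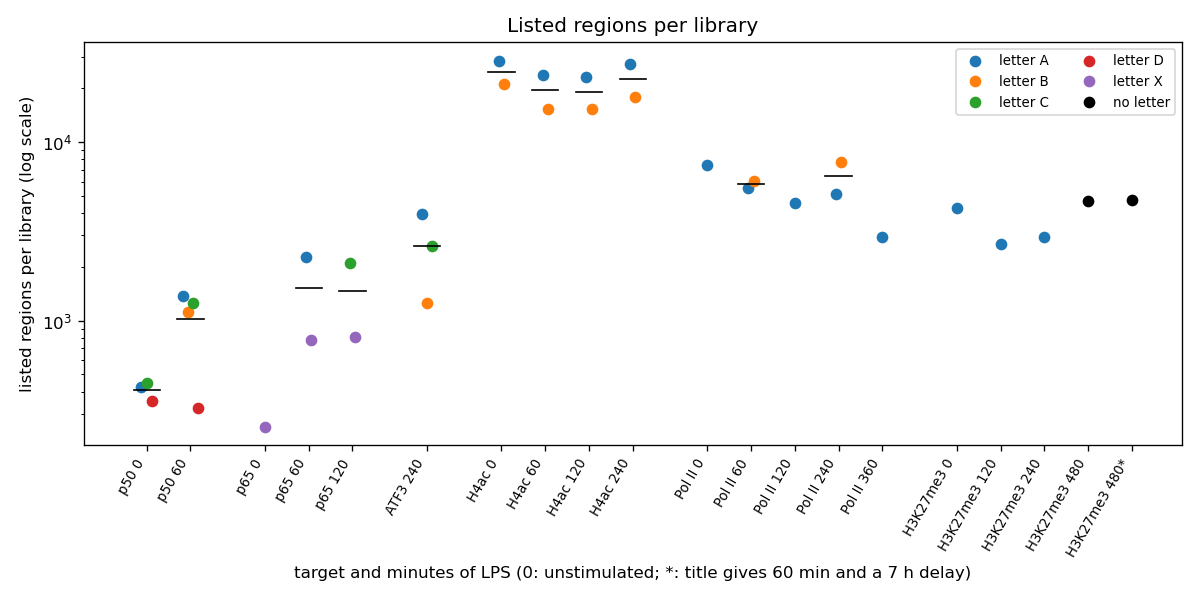
Number of listed regions in each of the 35 libraries (vertical axis, log scale) by target and minutes of LPS. Points are libraries coloured by the letter in the title and bars are group means. The LPS library of letter D, at 324 regions, lies below all 3 unstimulated p50 libraries, and the p50 libraries of letters A, B and C with LPS lie between 1118 and 1378.

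The LPS libraries of p50 listed 1018 ± 475 regions (SD, n = 4) and the unstimulated ones 408 ± 48.4 (n = 3), a ratio of 2.49. In letter A the number was 424 without and 1378 with LPS, and in letter C it was 447 and 1253. Letter D had 354 without and 324 with LPS, and the LPS library of letter B had 1118. The difference did not pass (exact two-sided permutation test, p = 0.229). No difference could pass 0.05, since 0.0571 is the smallest p that 3 against 4 libraries allow. The titles of the A and C libraries open with the same date in both conditions, and the D libraries share another, so the values by letter are also values within a date. Counted as covered base pairs, the ratio was 1.02 over all widths (exact permutation p = 0.971) and 2.43 up to the width limit (0.338 ± 0.166 against 0.139 ± 0.0331 Mb, exact permutation p = 0.229).

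At single sites, 238 p50 regions were gained with LPS and 16 were lost, out of 2478 merged regions. Another 148 were held by at least 3 LPS and at least 2 unstimulated lists, 44 by all 7 lists and 1481 by 1 list only. Only 53 of the 238 gained regions were also listed in LPS D. Among the 35 splits of the 7 libraries, the real one included, 2 gave at least 238 gained regions (at most 239) and 27 gave at least 16 lost ones. In simulated lists where 200 gained regions were planted, 172 further regions without an LPS effect of their own met the same rule. The gained count was 560 without LPS D and 373 without LPS B. It was 97 with all widths, as first planned, 129 with at least 50% of the merged region covered and 152 with the better-scored 50% of each list. With every library of a group required it was 42, and with letter as the block 389. The lost count was 25 without LPS B, 2 without unstimulated A, 6 without unstimulated C and 8 without unstimulated D. With lists of equal length, a setting chosen after seeing the data, 68 regions were gained, which no other split reached, and 29 lost.

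The best-ranked p50 regions in every list lay on chromosome 8 at 114244551 to 114250430, chromosome 5 at 31393611 to 31398120 and chromosome 7 at 134622151 to 134624210. Their scores, which are the authors' and rank regions within a list, were 3.4174 to 6.7181, 1.8471 to 6.4948 and 2.0636 to 6.1784. The region on chromosome 7 was also held by all 7 Pol II lists and 6 of 8 H4ac lists. The 5 best-ranked gained regions were all held by LPS A, B and C and not by LPS D. They lay on chromosome 10 at 20919031 to 20920820, chromosome 11 at 67905501 to 67905680 and 54785381 to 54789390, chromosome 10 at 77597761 to 77598160 and chromosome 12 at 56490541 to 56494450. The region of chromosome 10 that starts at 77597761 was held by 3 p65 lists as well, and none of the 5 was in an ATF3 or H3K27me3 list. The best-ranked lost region lay on chromosome 13 at 47678691 to 47680880, held by unstimulated A and D.

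In 3 of the 4 LPS libraries, most p50 regions lay in acetylated chromatin. The share touching the H4ac set was 59.7 ± 11.8% (SD, n = 4) with LPS and 41.7 ± 13.8% (n = 3) without, where random placement gave 3.35% and 3.31%. The LPS libraries of letters A, B and C had 64.6%, 64.1% and 67.9%, and LPS D had 42.2%. Unstimulated A, C and D had 51.9%, 47.2% and 26.0%. Shares touching Pol II were 36.6 ± 10.2% with LPS and 25.0 ± 7.08% without, and those touching H3K27me3 10.7 ± 1.57% and 11.3 ± 1.70%. Mean shares were lower with LPS for p65 (8.30 ± 5.30% against 12.3 ± 1.75%) and ATF3 (4.22 ± 2.82% against 9.62 ± 1.19%). In every p50 library, overlap with each of the 5 other targets exceeded random placement (permutation p = 0.002, the smallest possible, adjusted p = 0.00221). Pooled over letters and dates, no difference between conditions exceeded the spread of libraries. The exact permutation p was 0.171 for H4ac and Pol II, 0.114 for ATF3, 0.229 for p65 and 0.571 for H3K27me3, with a Benjamini-Hochberg value over 9 contrasts of at least 0.257. With each region shifted within 1 Mb in place of random placement, the overlap of p50 with H3K27me3 under LPS was 1.22 times the random level and no longer passed in every library.

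Within letters A, C and D, each of 1 date in both conditions, the shares with H4ac and Pol II were higher with LPS in all 3 and those with ATF3 lower in all 3. With Pol II they were 43.0%, 42.5% and 21.4% with LPS and 30.0%, 28.1% and 16.9% without. With ATF3 they were 2.88%, 2.54% and 8.44% against 10.0%, 8.29% and 10.6%. With p65 letter D ran the other way, at 5.92%, 5.08% and 16.2% against 14.1%, 10.6% and 12.4%, and the difference of -4.03 percentage points was -6.67 without LPS D. The difference for H4ac was 18.0 points, and 10.1 without unstimulated D, and that for Pol II 11.6 and 7.51. The H4ac and Pol II sets came mostly from LPS libraries, so the way they were built can favour higher shares with LPS. Most of the p65 set (539 of 860 regions) was held by both p65 A at 60 min and p65 C at 120 min, and most of the ATF3 set (392 of 591) by both ATF3 B and ATF3 C, libraries that shared regions between the antibodies and rarely touched H4ac. With the p65 set from letter X and the ATF3 set from letter A, chosen after seeing the data, the differences were -1.55 and -0.394 points (exact permutation p = 0.571 and 0.857).

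**Figure D2:**
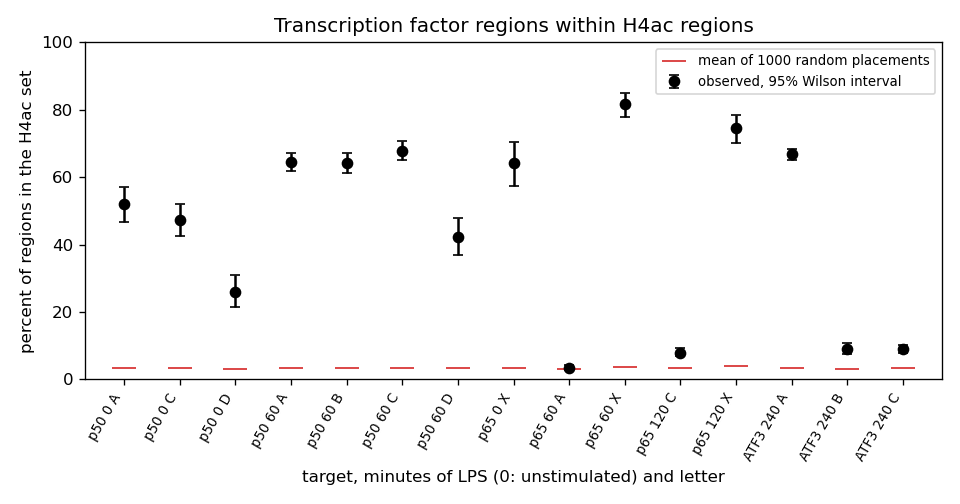
Percent of regions touching the H4ac set (vertical axis) for each p50, p65 and ATF3 library. Black points are observed shares with 95% Wilson intervals, and red dashes are means of 1000 random placements. The p65 libraries of letters A (3.40%) and C (7.94%) and the ATF3 libraries of letters B (8.91%) and C (8.86%) are the lowest 4, and all other libraries lie at 26.0% or above.

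The gained p50 regions touched H4ac held by both unstimulated libraries in 38.2% of cases (91 of 238, 95% Wilson interval 32.3 to 44.5). For the 148 regions held in both conditions it was 50.7% (42.7 to 58.6). With H4ac of both 60 min libraries the shares were 45.4% and 53.4%, and with Pol II 46.6% and 43.9%. Of these 3 contrasts, only that with unstimulated H4ac passed (Fisher's exact test, adjusted p = 0.0258), against 0.165 for H4ac at 60 min and 0.687 for Pol II. Gained regions were narrower, with a median width of 280 bp against 1450 bp, and a wide region meets another by chance more often.

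H4ac libraries listed 20414 ± 4944 regions (SD, n = 6) with LPS and 24790 ± 5278 (n = 2) without, a ratio of 0.823. In letter A there were 28522 regions unstimulated and 23682, 23028 and 27235 at 60, 120 and 240 min. In letter B there were 21058 unstimulated and 15392, 15256 and 17894 at those times, all from libraries of 1 date. The 240 min library of letter A has another date than the other letter A libraries. Each of the 6 LPS libraries was thus below the unstimulated library of its letter. Pooled over letters, which differed in level, the difference did not exceed the spread of libraries (exact two-sided permutation test, p = 0.429, smallest possible 0.0714).

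At single sites, H4ac regions held by both unstimulated libraries and neither LPS library outnumbered those of the opposite kind at every time. At 60 min 3118 regions were lost and 659 gained, at 120 min 3855 and 939, and at 240 min 2701 and 1360, of 24406 merged regions. Lost regions were 23.0%, 28.5% and 19.9% of the 13548 held by both unstimulated libraries. The highest count from any other split of the same 4 libraries was 1295, 1109 and 1341. Only 3 distinct splits exist, too few for a p under 0.05. With all widths, as first planned, wide regions joined most others. Then 328, 366 and 288 regions were lost and 29, 46 and 93 gained, where the highest other splits gave 172, 138 and 146. With regions up to 1 kb the lost counts were 1107, 1189 and 1020, the gained counts 967, 851 and 980 and the highest others 867, 817 and 1052. Lost regions then outnumbered gained ones by far less, and at 240 min neither count exceeded another split. With lists of equal length, chosen after seeing the data, 1959, 2316 and 1965 regions were lost and 1290, 1609 and 1638 gained, where the highest other splits gave 358, 326 and 423. Without the LPS library of letter B the gained counts were 1942, 2564 and 3289, and without unstimulated A they were 1539, 1721 and 2356. Without the LPS library of letter A the lost counts were 5764, 6228 and 5091, and without unstimulated B they were 6098, 7112 and 5488.

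**Figure D3:**
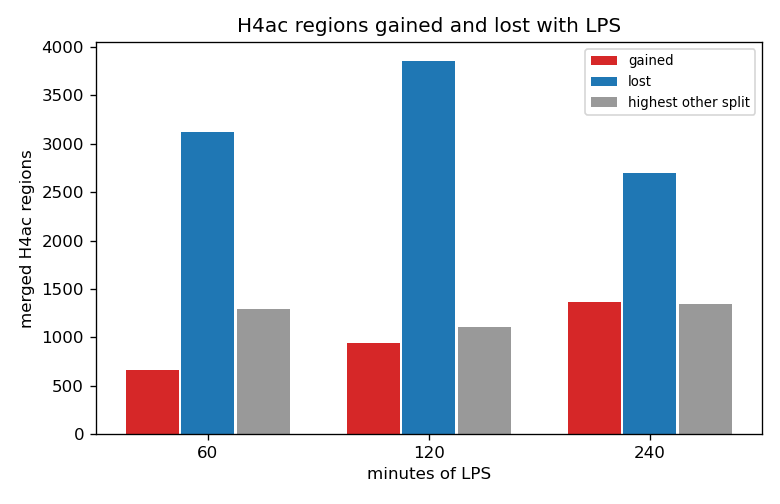
Merged H4ac regions (vertical axis) gained and lost at each time of LPS, with the highest count from any other split of the same 4 libraries. Lost regions (3118, 3855 and 2701) exceed that count at each time, and gained regions do so at 240 min alone (1360 against 1341).

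The best-ranked gained H4ac region lay on chromosome 14 at 63741371 to 63752780 and was held by both 60 min libraries alone. Regions on chromosome 1 at 58767711 to 58785760 and 74441911 to 74443270 were held by all 6 LPS libraries and neither unstimulated one, and all 7 Pol II lists held a region at each. A region on chromosome 4 at 144834211 to 144842820 was held by both 240 min libraries alone. Of the best-ranked lost regions, that on chromosome 7 at 106821741 to 106824840 was held by both unstimulated libraries and no LPS library. Those on chromosome 6 at 129178831 to 129188850 and chromosome 16 at 96045581 to 96062180 were held by the unstimulated and 60 min libraries and by none at 120 or 240 min. The best-ranked regions in every H4ac list lay on chromosome X at 166410111 to 166437670, chromosome 1 at 90172421 to 90175130 and chromosome 2 at 90921801 to 90939640. That on chromosome X was also held by lists of every other target.

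Many H4ac losses lasted. Of the regions lost at 60 min, 78.3% (95% Wilson interval 76.8 to 79.7) were also lost at 120 min and 61.8% (60.1 to 63.5) at 240 min. Simulated unchanged lists gave 44.8% and 30.9% (at most 47.0% and 33.7% in 100 sets), and independent lists 28.5% and 19.9%. Gained regions of 60 min were gained at 120 min in 51.1% of cases (47.3 to 54.9) and at 240 min in 42.0% (38.3 to 45.8), against simulated 17.1% and 27.2%. All these comparisons use the same 2 unstimulated libraries, so part of the excess over either value can come from those libraries. The simulated lists also ignore letter and date, which most lists of a letter share, so part can come from these too.

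H4ac lists of the same time resembled each other more than lists of different times. The mean Jaccard index was 0.445 ± 0.0409 (SD) for the 4 pairs of the same time. It was 0.357 ± 0.0545 for different times of the same letter and 0.321 ± 0.0389 for different times and letters. The difference of 0.106 between same and different times was reached by 2 of all possible pairings, the real one included (exact permutation test, one-sided, p = 0.019). With regions up to 1 kb the difference was 0.0363 and another pairing reached 0.0555. Of the 8 libraries, 5 were most similar to the other library of their own time. Unstimulated lists had an index of 0.308 ± 0.0389 with LPS lists, and LPS lists of different times 0.370 ± 0.0397 with each other.

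H4ac regions gained at 60 min held p50 more often than lost ones. A p50 region of at least 2 LPS libraries lay in 9.86% of gained regions (65 of 659, 95% Wilson interval 7.81 to 12.4) and 1.15% of lost ones (36 of 3118, 0.835 to 1.59). The ratio of shares was 8.54 at 60 min, 3.54 at 120 min and 1.99 at 240 min. Gained regions were wider, at medians of 3950 against 2210 bp, 3320 against 2400 bp and 2870 against 2090 bp, and a wide region meets another by chance more often. Relative to random placement of the same regions, p50 was 54.2, 34.1 and 24.1 times as frequent in gained regions at these times. In lost regions it was 8.17, 13.2 and 14.7 times as frequent. A p50 region of the unstimulated libraries lay in 2.43% of gained and 0.449% of lost regions at 60 min (ratio 5.41), in 1.38% and 0.519% at 120 min (2.67) and in 0.662% and 0.444% at 240 min (1.49), so the excess was not limited to p50 under LPS. The ratio for p65 of letter X at 60 min was 4.73, 2.61 and 0.745, from at most 11 regions in a set. ATF3 regions of the letter A library lay in 24.3% of gained and 9.30% of lost regions at 60 min, and Pol II of the same time in 22.8% and 6.77%. Unstimulated Pol II lay in 13.5% of both at 60 min, in 11.6% of gained and 17.7% of lost regions at 120 min and in 11.9% and 13.1% at 240 min. H3K27me3 lay in 10.5% of gained and 4.49% of lost regions at 60 min, in 7.56% and 4.93% at 120 min and in 5.96% and 5.00% at 240 min. Fisher's exact test with Benjamini-Hochberg adjustment gave 1.12e-25 for p50 at 60 min, 2.85e-12 at 120 min and 0.000971 at 240 min. It gave 1.70e-05, 0.0108 and 0.386 for unstimulated p50 and 0.0136, 0.0834 and 0.777 for p65 at the 3 times. At 60 min it gave 1.36e-22 for ATF3, 3.31e-29 for Pol II of the same time, 1 for unstimulated Pol II and 5.15e-08 for H3K27me3. At 120 and 240 min it gave 8.61e-06 and 0.305 for unstimulated Pol II and 0.00347 and 0.244 for H3K27me3. These tests were chosen after the lists had been examined. H4ac regions in all 8 lists held p50 of LPS in 4.08% of cases. That was below the share in gained regions at 60 and 120 min (Fisher's exact test, adjusted p = 5.13e-09 and 0.000933), and at 240 min the difference from 3.75% did not pass (0.664). At 60 min regions in all 8 lists held ATF3 of letter A in 10.96% of cases and H3K27me3 in 3.36%, below gained regions (Fisher's exact test, adjusted p = 9.20e-19 and 1.27e-13). They held p65 of letter X in 4.29% of cases, against 0.910% of gained regions, Pol II of the same time in 30.5% and unstimulated Pol II in 48.8%, all above gained regions (Fisher's exact test, adjusted p = 2.57e-06, 5.70e-05 and 1.45e-73).

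When regions were limited to 1 kb the p50 ratio of gained to lost H4ac regions was 1.68 (Fisher's exact p = 0.117), 0.740 and 0.446 at 60, 120 and 240 min, and the ATF3 ratio at 60 min 1.14 (Fisher's exact p = 0.523). Without LPS B of H4ac the p50 ratio was 3.97 at 60 min, 1.67 at 120 min and 1.11 (p = 0.554, Fisher's exact test) at 240 min. Without unstimulated B of H4ac it was 12.8 at 60 min and 3.02 at 240 min.

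ATF3 of letter A lay in 15.1% of gained and 12.5% of lost H4ac regions at 120 min and in 14.3% and 9.37% at 240 min (Fisher's exact test, adjusted p = 0.0453 and 8.54e-06). The ratio of shares was 2.61, 1.21 and 1.52 at 60, 120 and 240 min. It was 1.30, 0.645 and 0.787 without LPS B of H4ac and 3.99, 1.89 and 2.46 without unstimulated B. At 120 min it was 1.15 (Fisher's exact p = 0.0593) without unstimulated A. The ratios at 120 and 240 min were under 1 with regions up to 1 kb (0.914 and 0.937) and with all widths (0.339 and 0.774), and that at 120 min with lists of equal length (0.976). The difference between times was not tested.

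**Figure D4:**
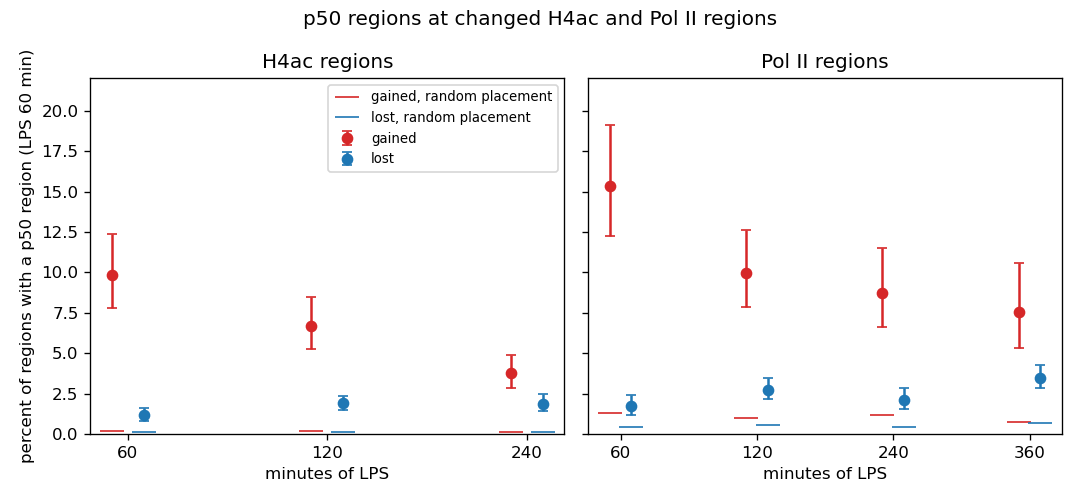
Percent of gained (red) and lost (blue) H4ac regions (left) and Pol II regions (right) that hold a p50 region of at least 2 LPS libraries, by minutes of LPS. Points are shares with 95% Wilson intervals and dashes are means of 200 random placements of the same regions. The H4ac shares of gained regions are 9.86%, 6.71% and 3.75%, and those of lost regions 1.15%, 1.89% and 1.89%.

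Pol II regions were lost more often than gained at each time against the single unstimulated library, with no replicate of that library. No LPS library of Pol II has the date of the unstimulated one, so date cannot be told apart from LPS. Lost and gained regions numbered 1759 and 423 at 60 min, 2429 and 611 at 120 min, 1890 and 515 at 240 min and 2665 and 398 at 360 min, of 5971 merged regions. Median listed widths were 1980 bp unstimulated, 3580 and 6520 bp at 60 min, 4150 bp at 120 min, 4645 and 5460 bp at 240 min and 1040 bp at 360 min. The unstimulated list held 7436 regions and the 360 min list 2948. No test of these counts was run. Gained regions at 60 min numbered 869 without library A and 787 without library B, and those at 240 min 1233 without A and 798 without B. With lists of equal length, lost and gained regions numbered 942 and 449 at 60 min, 1124 and 751 at 120 min, 1073 and 470 at 240 min and 1066 and 829 at 360 min.

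The best-ranked Pol II regions in every list lay on chromosome 5 at 143656691 to 143668480, chromosome 19 at 10004231 to 10062280 and chromosome 11 at 81784871 to 81862420. Gained regions on chromosome 16 at 84701601 to 84727060, chromosome 2 at 46214521 to 46215940 and chromosome 4 at 102243051 to 102282230 were held by all 6 LPS libraries. The region on chromosome 4 was in all 8 H4ac lists and that on chromosome 2 in none. Regions on chromosome 17 at 84580671 to 84583250 and chromosome 1 at 89516871 to 89520270 were in the unstimulated list alone. Of Pol II regions lost at 60 min, 79.9% were also lost at 240 min, against 55.7% for simulated unchanged lists and 49.3% for independent ones, with the unstimulated library shared between both comparisons and letter and date not simulated. At 360 min 90.3% of them were lost, not above the highest simulated value (90.9%, mean 88.1%), and 21.5% of regions gained at 60 min were gained, below the simulated mean of 29.7%.

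The p65 lists of letter X resembled each other, and not those of letters A and C. The letter X libraries listed 255 regions unstimulated, 782 at 60 min and 814 at 120 min, while the 60 min library of letter A listed 2285 and the 120 min library of letter C 2110. Up to the width limit of 10 kb, letter X held 209, 487 and 451 of these, letter A 2257 and letter C 2081. The comparisons that follow use regions within that limit. Within letter X, 363 merged regions were in the 60 min list alone, 104 in the unstimulated list alone and 99 in both. At 120 min these numbers were 321, 106 and 97. Each letter X library has a date of its own, so date cannot be told apart from LPS here. Of the X regions at 60 min, 55.7% were also in the X list at 120 min, and of the letter A regions at 60 min 0.227% were in the X list of the same time and 24.6% in the letter C list at 120 min. The H4ac set held 81.6% of X regions at 60 min, 74.5% at 120 min and 64.2% unstimulated, but 3.40% of the letter A regions, for which random placement gave 3.15% (permutation p = 0.521). It held 7.94% of the letter C regions, against 3.23% by random placement.

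For p65, 1 region was gained in both libraries at 60 min and 26 at 120 min, and 103 and 106 regions of the unstimulated list were in neither library of the time, with no test run. At 60 min the gained number was 364 without library A and 2198 without library X, and at 120 min 341 without C and 2030 without X. With all widths, as first planned, 52 and 80 regions were gained at 60 and 120 min, and with lists of equal length 0 and 3. A gained region on chromosome 10 at 77597301 to 77600110 was held by both X libraries with LPS and by letter C, and overlapped a gained p50 region. Gained regions on chromosome 4 at 129636861 to 129637130 and chromosome 2 at 153024071 to 153024510 were held by both 120 min libraries. The region on chromosome 2 was in all 7 p50 lists and all 8 H4ac lists.

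ATF3 regions at 240 min of LPS were mostly seen in 1 library. The libraries of letters A, B and C listed 3954, 1257 and 2604 regions. Of 6627 merged regions, 13 were in all 3 lists and 6036 in 1 list, and the lists of B and C shared 392, those of A and C 135 and those of A and B 90. The number shared was 390 without library A, 135 without B and 89 without C. In all 3 lists it was 66 with all widths, as first planned, and 5 with lists of equal length. It was 4 both with the better-scored 50% of each list and with at least 50% of the merged region covered. The H4ac set held 66.7% of the letter A regions, 8.91% of B and 8.86% of C, against 3.38%, 3.12% and 3.24% by random placement (permutation p = 0.002 for each, the smallest possible). Of the p65 regions of letter A at 60 min, 16.4% were in ATF3 list B and 25.3% in ATF3 list C. Regions in all 3 ATF3 lists included chromosome X at 166428921 to 166429130 and 166432931 to 166433580 and chromosome 3 at 103499441 to 103499730. Both regions of chromosome X were in all 8 H4ac lists, and that on chromosome 3 was in none and in 3 H3K27me3 lists. The regions of chromosome X lie in stretches held by 30 and 32 of the 35 lists, each with lists of all 6 targets, so they are not particular to ATF3. ATF3 had no unstimulated library, so no change with LPS was measured.

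H3K27me3 covered 77.8 Mb in the unstimulated list up to the width limit, and 45.7% of it was listed again at 120 min, 50.2% at 240 min, 68.0% at 480 min and 69.6% in the library with the 7 h delay. Of 2825 unstimulated regions, 56.8% (95% Wilson interval 54.9 to 58.6), 62.6%, 85.1% and 85.7% were overlapped in these lists, in the same order. Of 3294 merged regions, 1068 were in all 5 lists, 194 in the unstimulated list alone and 11 in all 4 LPS lists and not the unstimulated one. Regions in every list included chromosome 7 at 151550911 to 151660890, chromosome 3 at 87995111 to 88062130 and chromosome 9 at 72470301 to 72558070. A region on chromosome 17 at 37178721 to 37189940 was in the 4 LPS lists, and one on chromosome 6 at 48634241 to 48700450 in the unstimulated list alone. With all widths, as first planned, the kept shares of base pairs were 67.0%, 74.2%, 77.8% and 76.1%. Regions over 100 kb, which the width limit leaves out, made up 27.4% of the unstimulated list. They made up 38.3%, 35.04%, 25.5% and 24.5% of the LPS lists, in the same order. Up to the limit, a stretch under such a region counts as not listed unless a narrower region also covers it. With lists of equal length, chosen after seeing the data, the kept shares were 67.7%, 68.2%, 68.0% and 69.9%. There was 1 library per group. The 120 and 240 min libraries share a date, the 480 min and delay libraries another, and the unstimulated library has its own, so date cannot be told apart from the step between those pairs or from LPS.

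Pol II and H4ac lay together. Pol II regions touched the H4ac set in 88.0% of cases unstimulated (9.53% by random placement) and in 81.7 ± 7.10% (SD, n = 2) at 60 min and 75.9 ± 8.44% (n = 2) at 240 min. In letter A, that of the unstimulated library, the shares were 86.7%, 83.3%, 81.9% and 83.4% at 60, 120, 240 and 360 min. In letter B they were 76.6% at 60 min and 70.0% at 240 min. Unstimulated Pol II regions touched H3K27me3 in 3.19% of cases, below the 5.83% of random placement (permutation p = 0.002, the smallest possible), or 0.547 times. The ratio was 0.754 and 0.868 at 60 min (A and B) and 0.809 at 240 min (B), which passed, and 0.899 at 120 min, 0.916 at 240 min (A) and 0.931 at 360 min, which did not (permutation test, adjusted p = 0.188, 0.206 and 0.460). The reverse overlap, of unstimulated H3K27me3 with Pol II, was 0.892 times the random level (permutation test, adjusted p = 0.0742). It passed at 480 min (0.766) and in the library with the delay (0.730), and not at 120 or 240 min (0.997 and 0.938). H4ac regions touched the Pol II set in 44.5 ± 3.65% (n = 6) of cases with LPS and 35.04 ± 2.45% (n = 2) without. In letter A the shares were 41.6%, 41.8% and 40.7% at 60, 120 and 240 min against 33.3% unstimulated. In letter B they were 48.5%, 49.0% and 45.3% against 36.8%. The difference of 9.44 percentage points between the means had an exact permutation p of 0.0714, the smallest that 2 against 6 libraries allow, and a Benjamini-Hochberg value of 0.257. A set region had to be held by at least 2 Pol II libraries, and only 1 of these was unstimulated. Every region of the Pol II set was thus listed with LPS, which can favour higher shares in LPS libraries. Of the 175 tests of single libraries, 164 passed an adjusted p of 0.05, with 151 above and 13 below random placement. When each region was shifted within 1 Mb in place of random placement, the overlap of unstimulated H3K27me3 with H4ac went from 1.21 times to 0.670 times the random level.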

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

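The test of H4ac at the regions shared between 4 libraries and the test of swapped letter D labels were chosen only after the results they weigh had been seen. The test of H4ac regions under wider ones was also chosen after those results, but its bounds were set before its values were computed.

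ATF3 libraries B and C and the p65 libraries of letter A at 60 min and letter C at 120 min shared 1195 regions between the antibodies. These regions touched the H4ac set 1.17 times as often as random placement (4.02% against 3.42%, permutation p = 0.320), so few of them lay in listed H4ac regions. These libraries were already known to touch H4ac rarely, and open chromatin was not measured. The value therefore cannot decide whether both factors bound at the same open chromatin. The pair of 1 date shared 0.966 times as much as the 3 pairs of different dates (22.8% against 23.7 ± 1.44%, SD). Sharing was thus not higher on a shared day. This cannot decide on a batch over a longer period. The dates of these libraries follow one another, with no other library of the series between them. Signal that any antibody collects at fixed places remained open, since 16.2% of the regions (194 of 1195) were in a p50 list, against 0.102% by random placement. No biological explanation other than shared open chromatin was looked at.

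In letter D the p50 list did not exceed the unstimulated one in length with LPS, unlike in letters A and C. A swap of the labels was argued against, since LPS D regions were found in LPS A, B and C more often than unstimulated D regions, by at least 14.8 percentage points. An absent response was argued against as well: of 230 regions in LPS A, B and C and not in unstimulated A or C, LPS D held 44 and unstimulated D 3, a ratio of 14.7 (Fisher's exact p = 3.36e-11). Weaker detection in LPS D remained open. The regions it shared with LPS A, B and C had a median score percentile of at least 81.2 in those lists. A short list can share mainly the best-ranked regions of longer lists whatever made it short, and no other list was taken as a reference, so this value cannot decide. Read depth is unknown, so detection could not be measured directly. Of the LPS D regions, 11.7% to 19.5% were in each of ATF3 lists B and C and p65 lists A and C. Of the unstimulated D regions, 17.8% to 20.8% were. The ranges were 1.22% to 8.54% for LPS A, B and C, and 7.54% to 18.9% for unstimulated A and C. What this sharing means for letter D was not tested.

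Every H4ac library with LPS listed fewer regions than the unstimulated library of its letter. Joining of neighbouring regions remained open: covered base pairs up to the width limit were 0.787 times as high with LPS, but regions joined past 10 kb leave that measure, the ratio over all widths was 0.971, and the share of regions over 10 kb was higher in 6 of 6 LPS libraries, although their number up to 100 kb was lower in 6 of 6. At most 16.3% of lost regions lay under a region of 10 to 100 kb in both LPS lists of a time. This lies between the bounds of 10% and 50%, which were set before the share was computed. At that time, 60 min, 19.9% of regions held by all 4 lists lay under such a region. Loss at the same sites in both letters may account for part of it: lost regions were at least 2.01 times the highest other split at 10 kb, although with regions up to 1 kb the count at 240 min was 1020 against 1052. Weaker detection with LPS remained open, since lost regions had a median score percentile of up to 42.5 in the unstimulated lists.

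Chance could not be excluded for the p50 regions gained with LPS: 2 of the 35 splits gave at least 238, and the highest other, 239, came from LPS A, B and C with unstimulated A. With lists of equal length, chosen after seeing the data, only the real split reached its count of 68 (highest other 53). In every other setting at least 2 splits reached the real count. For the p50 regions lost, 27 of the 35 splits gave at least 16, and the highest other gave 507 when LPS A, B and C formed the group of 3, a structure that sets these 3 long lists against the shorter ones of LPS D and the unstimulated libraries.

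In the 4 LPS libraries of p50, 1 library stood far from the others in 5 of 10 measures. Chance gives about 1 in 20 for a measure without ties, and the measures are not independent, so their number cannot be set against that rate. The gap over the range was 0.919 for the share with p65, 0.915 for ATF3, 0.853 for H4ac and 0.835 for Pol II, each from letter D. It was 1 for median width, from letter A at 170 bp against 150 bp, where equal values in all other libraries force it to 1.

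The number of H3K27me3 regions minus the unstimulated number was -1593 at 120 min and -1335 at 240 min, but 368 at 480 min and 427 in the library with the 7 h delay. These opposite directions came from 1 library per group, the 120 and 240 min libraries share a date and the other 2 LPS libraries another, and the difference was not tested.

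Although the mice were female, 131 regions on chromosome Y were listed, in 25 lists. The comparisons of merged regions left out 44144 regions over the width limit of their target, of which 16877 were wider than 100 kb.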

How the results depend on the processing

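The width settings, equal list lengths, covered base pairs up to the width limit, removal of both letter D libraries, single-library removals for overlaps, and all tests of gained against lost regions were chosen after the data had been seen. Over 63 results, 212 of 310 alternatives kept the call and direction, as did 190 of 230 removals of 1 library, while 10 and 7 reversed it. Across every alternative run, 23 results kept both. The 2 alternatives of gene list occupancy were not run, since the gene table is on another build. Unknown depth limits every count, and except where stated the cause was not tested.

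With all widths, wide regions joined most others, so most counts fell by construction. Gained p50 regions numbered 97. H4ac regions gained and lost numbered 29 and 328 at 60 min, 46 and 366 at 120 min, and 93 and 288 at 240 min. Pol II regions gained and lost were 67 and 363 at 60 min, 71 and 509 at 120 min, 64 and 386 at 240 min, and 63 and 553 at 360 min. Gained p65 regions were 52 and 80 at 60 and 120 min, 66 ATF3 regions were in all lists, and H3K27me3 kept 67.0%, 74.2%, 77.8% and 76.1% of base pairs (120, 240, 480 min and delay). The p50 share at gained over lost H4ac regions was 3.10 at 240 min (Fisher's exact p = 0.159). For p50 at Pol II regions it was 3.01 at 60 min (Fisher's exact p = 0.0509), 3.02 at 240 min (0.0759) and 1.37 at 360 min (0.572). The ATF3 share reversed at H4ac regions to 0.339 at 120 min and 0.774 at 240 min and at Pol II regions to 0.856 at 360 min, and was 1.25 at Pol II regions at 120 min.

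With the narrower limits (1 kb, or 10 kb for Pol II and H3K27me3), lost H4ac regions numbered 1107, 1189 and 1020 at 60, 120 and 240 min and gained ones 967, 851 and 980. Gained Pol II regions were 1026 at 120 min and 845 at 360 min, gained p65 regions 2 and 15, and H3K27me3 kept 33.5%, 37.9%, 60.1% and 58.6%. The difference in similarity between H4ac lists of the same and of different times was 0.0363, against 0.106 at the width limit. At H4ac regions the gained over lost share of p50 was 1.68 at 60 min and reversed to 0.740 and 0.446 at 120 and 240 min. That of ATF3 was 1.14 and reversed to 0.914 and 0.937.

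With equal list lengths, 68 p50 regions were gained (the only 1 of 35 splits to reach this, highest other 53) and 29 lost. H4ac regions gained and lost were 1290 and 1959 at 60 min and 1609 and 2316 at 120 min. Lost Pol II regions were 942, 1124, 1073 and 1066 at 60, 120, 240 and 360 min, with 829 gained at 360 min. Gained p65 regions were 0 and 3, ATF3 regions in all lists 5, and H3K27me3 kept 67.7% and 68.2% at 120 and 240 min. The ATF3 share at gained over lost regions reversed to 0.976 for H4ac at 120 min and was 1.29 for Pol II at 360 min (Fisher's exact p = 0.0680).

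With the better-scored 50% of each list, 152 p50 regions were gained and 5 lost, 1737 Pol II regions were lost at 360 min, 0 and 8 p65 regions were gained at 60 and 120 min, and 4 ATF3 regions were in all lists. H3K27me3 then kept 48.5%, 52.1%, 71.5% and 72.6%. With 50% of the merged region covered, 129 p50 regions and 0 and 10 p65 regions were gained and 4 ATF3 regions shared. With regions within 1000 bp joined, 2 and 17 p65 regions were gained. In 1 kb bins, H4ac gained 4714, 5891 and 7863 and lost 12764, 15573 and 11211, since a region spans several bins. With every library of a group required, 42 p50 regions were gained and 0 lost, as a stricter rule must give fewer. Without both letter D libraries, 563 were gained and 10 lost.

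With 50% of a region covered, the difference between LPS and unstimulated H4ac in overlap with H3K27me3 reversed to 0.0348 percentage points, and unstimulated H4ac overlapped H3K27me3 at 0.791 times the random level (permutation p = 0.00995, the smallest possible with 200 placements). With regions shifted within 1 Mb, that overlap was 0.442, p50 with LPS overlapped H3K27me3 at 1.22, and H3K27me3 overlapped H4ac at 0.670, reversed from 1.21.

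Letters did not count as pairs: same-letter correlations between LPS and unstimulated p50 lists were 0.0753 for A, 0.0394 for C and 0.206 for D, although each exceeded the mean for other letters. With letter as the block, p50 regions gained and lost were 389 and 27, the ratio of region numbers 2.41 (exact permutation p = 0.5, smallest 0.25) and the H4ac ratio 0.816 (exact permutation p = 0.0625, the smallest possible).

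Leaving out 1 library gave 241 to 560 gained p50 regions (560 without LPS D, 373 without LPS B) and 2 to 25 lost (2, 6 and 8 without unstimulated A, C and D, 25 without LPS B). H4ac regions gained were 772 to 1942 at 60 min, 1071 to 2564 at 120 min and 1526 to 3289 at 240 min, highest without LPS B and next without unstimulated A (1539, 1721 and 2356). Those lost were 3314 to 6098, 4147 to 7112 and 2951 to 5488, highest without unstimulated B and next without LPS A (5764, 6228 and 5091). Gained Pol II regions were 787 (without B) to 869 (without A) at 60 min and 798 (without B) to 1233 (without A) at 240 min. Gained p65 regions were 364 (without A) to 2198 (without X) at 60 min and 341 (without C) to 2030 (without X) at 120 min, and shared ATF3 regions 89 (without C), 135 (without B) and 390 (without A). These counts rise by construction where fewer lists are required.

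The overlap of p65 at 60 min with H4ac was 1.08 to 22.2 times the random level (22.2 without A), and that of unstimulated H4ac with H3K27me3 0.746 to 0.959 (0.746 without A). The difference with LPS in overlap with H3K27me3 was -1.30 to 0.340 percentage points for p50 (0.340 without unstimulated A) and -0.502 to 0.496 for H4ac. The latter turned positive without LPS B of 60, 120 or 240 min (0.0306, 0.0886 and 0.119) and without unstimulated A (0.496). At H4ac regions the gained over lost share of ATF3 was 0.645 to 1.89 at 120 min (0.645 without LPS B, 1.15 without unstimulated A) and 0.787 to 2.46 at 240 min (0.787 without LPS B), and that of p50 1.11 to 3.02 at 240 min (1.11 without LPS B).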

Other observations

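The comparisons of gained with lost regions here were chosen after the data had been seen, and Pol II rests on 1 unstimulated library, whose date no LPS library of Pol II shares. Gained Pol II regions met H4ac regions gained at the same time in 10.9% of cases at 60 min, 12.9% at 120 min and 18.8% at 240 min, and lost Pol II regions in 0.966%, 1.52% and 1.64% (Fisher's exact test, adjusted p = 3.64e-20, 2.29e-29 and 1.30e-40). Pol II regions in all 7 lists met them in 7.92%, 10.9% and 15.7% of cases, and their difference from gained ones did not pass (Fisher's exact test, adjusted p = 0.128, 0.292 and 0.187). Gained regions were wider than lost ones, at medians of 30720 against 1060 bp, 17380 against 1810 bp and 26570 against 1100 bp, and a wide region meets another more often by chance. Relative to random placement of the same regions, gained Pol II regions met gained H4ac regions 9.89, 10.3 and 9.34 times as often, and lost Pol II regions 2.19, 2.02 and 2.06 times as often. Lost Pol II regions met lost H4ac regions in 16.8% of cases at 120 min and gained ones did so in 8.18% (Fisher's exact test, adjusted p = 5.92e-08). At 60 min these shares were 10.5% and 8.27% (Fisher's exact test, adjusted p = 0.244), and at 240 min 8.94% and 5.63% (adjusted p = 0.0195). Pol II regions in all 7 lists met lost H4ac regions more often than lost Pol II regions did, in 14.3%, 19.5% and 13.4% of cases at 60, 120 and 240 min. That difference passed at 60 and 240 min and not at 120 min (Fisher's exact test, adjusted p = 0.0111, 0.00150 and 0.123).

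Gained Pol II regions held p50 in 15.4% of cases at 60 min, 9.98% at 120 min, 8.74% at 240 min and 7.54% at 360 min, and lost ones in 1.71%, 2.72%, 2.12% and 3.49%. Fisher's exact test gave adjusted p-values of 8.04e-26, 2.57e-12, 2.34e-10 and 0.000824. Pol II regions in all 7 lists, with a median width of 51980 bp, held p50 in 20.2% of cases, a higher share than in gained regions, which did not pass at 60 min and passed at the later times (Fisher's exact test, adjusted p = 0.0590, 4.91e-07, 4.51e-08 and 1.74e-08). With all widths the ratio of shares no longer passed at 60 min (3.01, Fisher's exact p = 0.0509), 240 min (3.02, p = 0.0759) and 360 min (1.37, p = 0.572). At 60 min the ratio was 9.01, and it was 5.74 without Pol II library A, 5.19 without Pol II library B and 15.7 without LPS C of p50. At 240 min it was 4.13, and 2.57 without Pol II library A and 2.51 without B. Relative to random placement of the same regions, p50 was 11.9 times as frequent in gained and 3.81 times as frequent in lost regions at 60 min. The contrast was smaller later, at 10.2 and 4.68 at 120 min, 7.37 and 4.85 at 240 min and 10.0 and 5.32 at 360 min. For p65 of letter X the gained over lost ratio was 1.20, 0.753, 0.662 and 0.587 at the 4 times, and none passed (Fisher's exact test, adjusted p = 0.554, 0.310, 0.279 and 0.127). Relative to random placement, p65 was more frequent in lost than in gained regions at each time (13.4 against 5.25 at 60 min).

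A region on chromosome X at 166431871 to 166439090 was in 32 of the 35 lists, across all 6 targets. It overlapped the best-ranked of the merged H4ac regions held by all 8 H4ac lists (166410111 to 166437670). It also overlapped a p65 region held by all 5 p65 lists (166434091 to 166439000). Another on chromosome 11 at 3092821 to 3094300 was in 25 lists, also of all 6 targets. A region on chromosome 17 at 35516211 to 35517230 was in 21 lists, made up of 7 p50, 8 H4ac and 6 Pol II lists.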
